A study of Mus musculus with 2 samples.

How the data were processed

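Polyadenylated RNA above 200 nt from frontal cortex of C57BL/6J mice aged 8 weeks was sequenced by the authors as stranded paired-end reads of 101 nt, with ERCC spike-in RNAs added, in 2 biological replicates of 1 group. The labels describe the tissue as pooled from males and females. For each library the authors deposited a gene and a transcript quantification on mm10 with annotation release M4, per the deposited text description. The aligner and the quantification program are not given in the sources used here, and the columns have the layout of RSEM output. The deposited values used are expected counts (estimated fragments), TPM over all entries including spike-ins, and FPKM. Deposited posterior means and posterior SDs of counts were used as well. The deposited transcript quantifications also give the percent of a gene's TPM taken by each transcript, and the deposited interval bounds of TPM were read as 95% credibility intervals, a level that the files do not state. These bounds do not always contain the deposited TPM. For Meg3 in replicate 1 the TPM was 1939.65 and the bounds were 1913.88 to 1936.59. Each gene quantification has 69691 entries, of which 43346 are annotated genes, 26248 are tRNA-like, 96 are spike-ins and 1 is phiX. The transcript quantifications have 129984 entries.

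Symbols, biotypes and coordinates (mm10) came from GENCODE M21, matched by identifier without version for 42462 genes and 101510 of 103639 transcripts. Genes without a match were kept in counts of all genes.

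Expected counts summed to 106084891 in replicate 1 and 90476207 in replicate 2, of which annotated genes took 101771589 and 86854784. Spike-ins took 3.50% (Wilson interval 3.49 to 3.50%) and 3.47% (3.46 to 3.47%). Counting intervals of replicate ratios are exact conditional binomial intervals at 95%. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. With 2 libraries, SDs have 1 degree of freedom.

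Gene lists, gene pairs, thresholds, the named-gene rule and the alternatives to try were fixed before the data were examined. Replicate ratios are log2 of replicate 2 over replicate 1 of CPM with a prior count of 2 (CPM, counts scaled to the library total), scaled by TMM factors (1.02 and 0.982) from edgeR 4.0.16 in R 4.3.3 on rounded expected counts without spike-ins. For single sex-linked genes the ratios with counting intervals were taken without a prior count, whereas the median of the Y-linked list and the plot keep it. The biological coefficient of variation came from estimateDisp with an intercept after filterByExpr. List medians, over members with a mean of 1 TPM or more, were set against 10000 random lists of the same size matched on mean log2 CPM in 20 bins. A list counts as outside when its percentile is under 2.5 or above 97.5, and lists with under 3 such members got none. A pair ratio counts as beyond the spread when its sign is the same in both libraries, its mean exceeds its SD and the deposited intervals do not overlap in either library. The alternatives from posterior means and counts used sign and SD alone, and each single library used interval separation alone. Isoform use was taken over genes with a mean of 10 TPM or more and at least 2 transcripts. Spike-ins with 100 or more counts were set against 1000 draws from the 50 genes nearest in count. The chi-square test used genes with 10 or more counts over both libraries. No p-values were computed between replicates for genes. Values with no replicate error were called moved beyond 0.01 for r, 10% for the coefficient of variation, 50% for the spike-in SD and the Wilson interval for the isoform percent. Shares of composition are over all entries. The histone and ribosomal lists come from symbol patterns. The histone list holds copies that share reads, and its mRNAs are made mostly without a poly(A) tail.

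Genes named in the text are the 10 most abundant nuclear protein-coding genes, the 2 to 4 most abundant members of each list (1 for regions outside the cortex) with the members that bound its range, and the 10 highest and 10 lowest replicate ratios among protein-coding genes at 10 TPM or more with intervals apart. The genes of the 27 pairs and the fixed isoform genes, with values for the 10 most abundant, complete the rule. Some genes that the rule names are left out of the text but kept in the counts and medians. Other genes named, among them further noncoding RNAs and genes of other tissues, were chosen after their values were seen. The 4 X-linked genes that escape inactivation and the second placental list were chosen before their own values were examined. That choice came after the split in Xist and Y-linked genes and the first placental genes had been seen.

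Alternatives covered detection thresholds, posterior means, FPKM, pseudocounts, DESeq2 1.42.0 size factors, library size, the spike-in total, filters on low values, shares of counts in place of TPM, TPM rescaled to nuclear protein-coding genes and each replicate left out. Those on autosomal genes, on short effective lengths, on protein-coding genes for detection and on the spike-in total for lists were chosen after seeing the data. Lists of genes of 18 other tissues and a second list of placental genes were written after placental and fetal genes had been seen among the highest ratios. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data of 43346 genes, where a simulated coefficient of 0.1 was recovered as 0.0998, and as 0.114 with 200 genes changed by a log2 ratio of 1. Changed genes were recovered at 1.00 and −1.02, and a list of 12 raised genes reached percentile 100. No paired or group comparison was possible because there is 1 group.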

Results

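The series holds 1 group, frontal cortex of C57BL/6J mice aged 8 weeks, with 2 biological replicates sequenced as polyadenylated RNA depleted of ribosomal RNA. The labels describe the tissue as pooled from males and females. With 1 group there is no contrast between conditions, so levels within the tissue and differences between the replicates are given. Levels are deposited TPM, a length-adjusted share of transcripts, as mean ± SD (n = 2) unless single libraries are named. Expected counts summed to 106084891 in replicate 1 and 90476207 in replicate 2, and 14210 annotated genes reached 1 TPM in both libraries, 13033 of them protein-coding. These included 187 lincRNA, 181 antisense and 290 processed pseudogene loci, and 483 further genes reached 1 TPM in replicate 1 alone and 226 in replicate 2 alone.

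Apoe, the lipid transport protein made mainly by astrocytes in brain, was the most abundant nuclear protein-coding transcript at 3124 ± 2.85 TPM (ENSMUSG00000002985.11, chromosome 7, 19696109 to 19699188, mm10). The glycolytic enzyme gene Gapdh followed at 2805 ± 489 TPM, the protease inhibitor Cst3 at 2525 ± 75.9 TPM and the ferritin heavy chain gene Fth1 at 2275 ± 385 TPM. Rplp1, a ribosomal protein, stood at 1948 ± 110 TPM, the creatine kinase Ckb at 1903 ± 35.4 TPM, the elongation factor Eef1a1 at 1818 ± 138 TPM and the ubiquitin gene Ubb at 1711 ± 23.3 TPM. The respiratory chain subunit Cox6a1 reached 1448 ± 418 TPM and the calmodulin gene Calm2 1448 ± 20.7 TPM. The posterior SD that the authors give for Gapdh, 353 counts in replicate 1, is small beside its 225433 counts, although reads of Gapdh, Fth1, Rplp1 and Eef1a1 can be shared with processed pseudogenes. These 10 genes took 2.12 ± 0.0886% of all TPM.

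Genes of the mitochondrial chromosome took 34.4 ± 0.798% of TPM and 8.00 ± 0.363% of expected counts. The distance between the 2 shares came mainly from mt-Atp8, an ATP synthase subunit, which took 23.5 ± 1.15% of TPM and 0.179 ± 0.00593% of counts. Its effective length in the files was 10.4 nt in replicate 1 and 8.68 nt in replicate 2 (mitochondrial positions 7766 to 7969), so its TPM is not a level comparable with other genes. The cytochrome oxidase subunit mt-Co1 stood at 24762 ± 704 TPM. Nuclear protein-coding genes took 49.3 ± 1.66% of TPM and 82.1 ± 0.919% of counts. The 82 cytosolic ribosomal protein genes took 3.11 ± 0.170% of TPM and 1.15 ± 0.0278% of counts, and the 36 nuclear complex I genes 0.586 ± 0.00261% and 0.237 ± 0.00562%. Pseudogenes took 7.23 ± 0.589% of TPM and 2.20 ± 0.281% of counts, long noncoding genes 2.24 ± 0.127% and 3.37 ± 0.297%, and small noncoding genes 1.37 ± 0.405% and 0.107 ± 0.0278%. Of the pseudogene share of TPM, 6.09 ± 0.633 points were 5 copies of mitochondrial genes on chromosome 1, whose separate values are uncertain because of shared reads. The long noncoding share includes Gm42418, which overlaps ribosomal RNA sequence. That gene alone stood at 10925 ± 1039 TPM and had 1368673 and 1411971 counts in replicates 1 and 2.

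Markers of cortical excitatory neurons were led by Camk2a, a kinase of the postsynaptic density, at 707 ± 2.81 TPM (ENSMUSG00000024617.12, chromosome 18, 60925618 to 60988152). The vesicular glutamate transporter Slc17a7 stood at 424 ± 32.5 TPM (ENSMUSG00000070570.4, chromosome 7, 45163949 to 45176142) and Nrn1 at 77.7 ± 4.33 TPM. The subcortical paralog Slc17a6 stood at 3.86 ± 0.573 TPM. In the list of GABAergic genes, the neuropeptides Cck, Npy and Sst reached 685.0 ± 43.5, 368 ± 40.8 and 339 ± 32.2 TPM, and the GABA-synthesising enzyme Gad1 549 ± 115 TPM. Bulk levels do not show which cells made these transcripts, so they are not levels of GABAergic neurons alone. Pvalb stood at 24.9 ± 8.56 TPM and Vip at 26.9 ± 0.481 TPM. The upper layer genes Lamp5, Rasgrf2 and Cux1 were at 121 ± 25.2, 39.7 ± 2.23 and 33.5 ± 0.148 TPM, and the deep layer genes Syt6 and Tbr1 at 32.9 ± 1.23 and 25.4 ± 1.16 TPM.

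Glial genes were also abundant. The astrocyte enzymes Glul and Aldoc stood at 1225 ± 159 and 688 ± 20.7 TPM and the glutamate transporter Slc1a2 at 292 ± 4.09 TPM. The myelin genes Mbp and Mobp were at 1129 ± 207 and 277 ± 41.5 TPM, and the oligodendrocyte precursor genes Gpr17, C1ql1 and Pdgfra at 17.4 ± 0.0636, 11.2 ± 1.95 and 10.3 ± 1.98 TPM. C1qb and Ctss, expressed by microglia, were at 58.1 ± 12.3 and 42.4 ± 9.57 TPM. Ly6c1, Itm2a and Cldn5 of endothelial cells reached 107 ± 23.7, 57.7 ± 12.2 and 53.7 ± 2.67 TPM. Vtn, Rgs5 and Acta2 of mural cells reached 96.0 ± 9.89, 39.8 ± 9.50 and 17.3 ± 6.15 TPM. The meningeal genes Igf2 and Dcn were at 36.0 ± 8.53 and 12.2 ± 1.65 TPM, and the globin gene Hba-a2, of red blood cells, at 260 ± 43.8 TPM. No cell shares can be derived from these bulk levels.

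Genes known best from other brain regions were detected at a range of levels. Penk and Ppp1r1b of the striatum stood at 109 ± 9.76 and 65.4 ± 16.4 TPM, Doc2g and Th of the olfactory bulb at 155 ± 8.21 and 67.7 ± 1.56 TPM, and Zic1 of the cerebellum at 64.7 ± 8.37 TPM. Enpp2 of the choroid plexus reached 61.4 ± 0.424 TPM, although Ttr, the most abundant choroid plexus transcript, stood at 0.890 ± 0.0566 TPM. The highest member was Trh at 27.9 ± 0.346 TPM for the hypothalamus, Prkcd at 7.92 ± 0.785 TPM for the thalamus, Rarres2 at 5.90 ± 2.43 TPM for ependyma and Fibcd1 at 4.29 ± 0.509 TPM for the hippocampus. Median members were under 1 TPM for the choroid plexus, hippocampus and hypothalamus lists, at 0.80, 0.335 and 0.300 TPM, and for the histone list at 0.755 TPM. The other 34 of 38 lists had a median member at 1 TPM or more. Histone mRNAs are made mostly without a poly(A) tail, so libraries of polyadenylated RNA do not give their full levels. Rescaled to nuclear protein-coding genes alone, every level is multiplied by 1.98 in replicate 1 and 2.08 in replicate 2. Among genes of immature and dividing cells, Dcx stood at 25.7 ± 0.156 TPM, Sox4 at 19.5 ± 2.86 TPM and the proliferation gene Mki67 at 0.290 ± 0.0141 TPM.

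**Figure D1:**
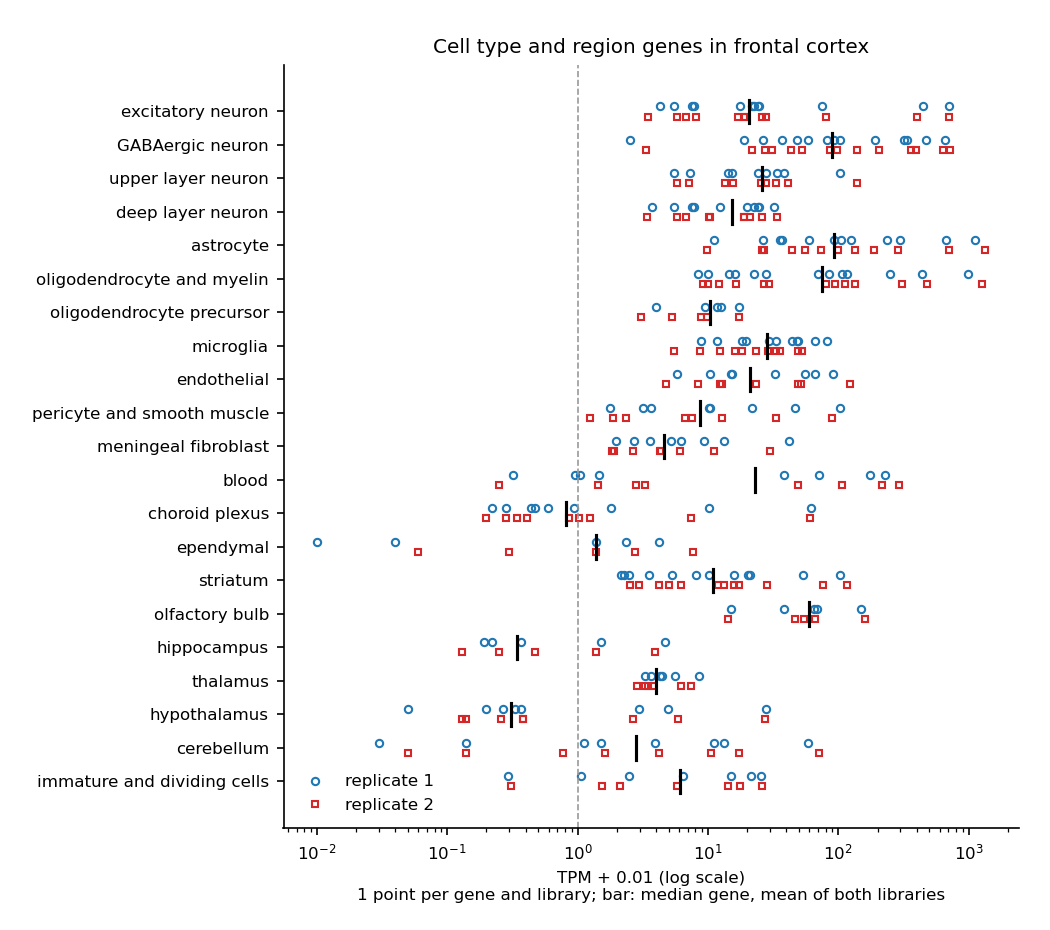
TPM of each member of the cell type and region lists on a log axis (0.01 added), 1 point per gene and library, with a bar at the median member averaged over both libraries. The bar stands at 89.6 TPM for GABAergic, 28.5 TPM for microglial and 0.300 TPM for hypothalamic genes.

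Ratios were taken between paralogs and between markers of cell classes. Slc17a7 exceeded Slc17a6 by 6.79 ± 0.10 on the log2 scale (SD, n = 2), the mature chloride exporter Slc12a5 exceeded the importer Slc12a2 by 3.38 ± 0.02, and Dnmt3a exceeded the embryonic methyltransferase Dnmt3b by 5.03 ± 0.30. The brain hexokinase Hk1 exceeded the muscle form Hk2 by 6.27 ± 0.05, Syt1 exceeded Syt2 by 6.56 ± 0.51 and Snap25 exceeded Snap23 by 6.99 ± 0.18. The adult sodium channels Scn2a and Scn1a exceeded the fetal form Scn3a by 1.97 ± 0.16 and 0.95 ± 0.11. Camk2a exceeded Camk2b by 1.22 ± 0.04, Chrm1 exceeded Chrm2 by 2.61 ± 0.15 and Ldhb exceeded Ldha by 1.95 ± 0.18.

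Glutamate receptor subunits differed as well. Gria2, the subunit that blocks calcium entry, exceeded Gria1 by 0.61 ± 0.19 and Gria4 by 1.74 ± 0.29 on the log2 scale. Grin2a stood under Grin2b by TPM, at −2.01 ± 0.32, and Grin2b over Grin2c at 0.24 ± 0.11. Slc17a7 exceeded the GABA transporter Slc32a1 by 2.34 ± 0.17, Gad1 exceeded Gad2 by 3.57 ± 0.42, Pvalb stood under Sst at −3.81 ± 0.37 and Sst over Vip at 3.65 ± 0.11. Slc1a2 exceeded Slc1a3 by 0.47 ± 0.22, Aldoa exceeded Aldoc by 0.69 ± 0.12, and Eno2 stood under Eno1 at −0.28 ± 0.06. For 26 of the 27 fixed pairs, not all of which are named, the ratio had 1 sign in both libraries, exceeded its SD and had non-overlapping intervals of TPM in both. The exception was the serotonin receptor pair Htr2c and Htr2a, at 0.57 in replicate 1 and −1.05 in replicate 2, mean −0.24 ± 1.14. The smallest two-sided p that an exact sign-flip test over 2 libraries can give is 0.5. Counts not divided by length give Grin2a over Grin2b −4.14, Grin2b over Grin2c 2.08, Sst over Vip 1.89, Gad1 over Gad2 1.97, Slc1a2 over Slc1a3 2.00 and Dnmt3a over Dnmt3b 6.49. They give Pvalb over Sst −2.83, Htr2c over Htr2a 0.47 and Aldoa over Aldoc 0.27, so the sizes of such ratios between genes rest on the transcript lengths assigned.

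Functional gene groups gave these levels. The presynaptic genes Snap25, Vamp2 and Syp stood at 1330.4 ± 24.3, 640.1 ± 26.8 and 490.2 ± 10.1 TPM, and the postsynaptic scaffold Dlg4 and kinase Camk2b at 336 ± 7.86 and 303 ± 6.57 TPM. The NMDA receptor subunit Grin1 and the AMPA receptor subunit Gria2 were at 161 ± 1.29 and 135 ± 28.8 TPM. The muscarinic receptors Chrm1 and Chrm4 were at 40.2 ± 2.52 and 19.0 ± 0.445 TPM. The chaperones Hspa8 and Hsp90aa1 were at 1022 ± 15.8 and 263 ± 43.6 TPM and the clock output genes Dbp and Tef at 126 ± 6.61 and 126 ± 8.41 TPM. The complex I genes Ndufa4 and Ndufb9 reached 631 ± 18.4 and 322 ± 43.6 TPM, the ribosomal protein genes Rps15 and Rpl41 1191 ± 61.8 and 1140 ± 198 TPM, and the histone genes Hist1h2bc and Hist2h2aa1 148 ± 7.52 and 92.9 ± 23.3 TPM. Hist2h2aa1 shares reads with near-identical copies, so its level is uncertain. Levels of histone genes are also limited by the selection of polyadenylated RNA. Tsc22d3 and Per1, induced by glucocorticoids, were at 40.5 ± 7.22 and 24.8 ± 3.78 TPM.

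Sex-linked transcripts separated the replicates. Xist, the noncoding RNA of the inactive X chromosome, had 107 counts in replicate 1 and 77696 in replicate 2 (chromosome X, 103460366 to 103483254), a log2 ratio of replicate 2 over replicate 1 of 9.78 with a counting interval of 9.51 to 10.07. The Y-linked translation factor Eif2s3y had 7150 and 3 counts (chromosome Y, 1010543 to 1028847), a ratio of −10.94 with an interval of −13.22 to −9.39. Ddx3y had 4584 counts and 1 count (chromosome Y, 1260771 to 1286629), with an interval of −17.19 to −9.40, and Kdm5d 4651 counts and 1 count (chromosome Y, 897788 to 956786), with an interval of −17.21 to −9.42. Uty had 1777 and 3 counts (chromosome Y, 1096861 to 1245759), a ratio of −8.93 with an interval of −11.21 to −7.38. In TPM, Xist stood at 0.250 and 110 and Eif2s3y at 53.8 and 0.05. Tsix, antisense to Xist, had 14.8 and 3.17 expected counts. Xist was thus abundant in replicate 2 alone and the Y-linked genes in replicate 1 alone, whereas the labels describe pooled sexes. Any other difference between these libraries cannot be separated from that split. Differences between the replicates have no replicate check.

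Immediate early genes, which neuronal activity induces, were higher in replicate 2 for all 19 members. Their median log2 ratio of replicate 2 over replicate 1 was 0.98, where random lists of the same size and level gave −0.07 to 0.08. The transcription factor gene Fos stood at 19.7 TPM in replicate 1 and 52.2 TPM in replicate 2, a log2 ratio of 1.62 with a counting interval of 1.56 to 1.69 (ENSMUSG00000021250.9, chromosome 12, 85473890 to 85477273). The synaptic regulator gene Arc stood at 46.3 and 107 TPM, a ratio of 1.34 with an interval of 1.30 to 1.37 (ENSMUSG00000022602.10, chromosome 15, 74669083 to 74672570). Egr1 and Nr4a1 averaged 76.9 ± 26.3 and 49.9 ± 23.3 TPM, with ratios of 0.85 and 1.12, and members ranged from 0.16 for Bdnf to 1.91 for Fosb.

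Glial, vascular and neuronal groups also lay apart between the replicates. All 11 microglial genes were lower in replicate 2, with a median log2 ratio of −0.41 from −0.57 for P2ry12 to −0.05 for Trem2, and all 8 mural cell genes were lower, with a median of −0.37 and the lowest value, −0.83, in the contractile gene Myh11. Endothelial genes had a median of −0.14, from −0.34 for Slco1a4 to 0.42 for Ly6c1, oligodendrocyte precursor genes −0.23, led downward by Pdgfra at −0.26, and meningeal genes −0.36, from −0.84 for Ogn to 0.40 for Col1a1. Myelin genes were higher in replicate 2 for 12 of 13, with a median of 0.26, 0.47 for Mbp and −0.14 for Ugt8a. GABAergic genes had a median of 0.23, from −0.64 for Cnr1 to 0.83 for Pvalb, upper layer genes 0.19, with Lamp5 at 0.55, and excitatory genes 0.11, with Camk2a at 0.15. Blood genes were higher for 7 of 7, with a median of 0.55, Hba-a2 at 0.45 and S100a9 at 1.69. Striatal genes had a median of 0.39, from −0.15 for Tac1 to 1.0997 for Drd2, and cerebellar genes 0.24.

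Of the functional groups, neuropeptide genes had a median log2 ratio of 0.27, from −0.65 for Adcyap1 to 0.38 for Pdyn, and glucocorticoid response genes 0.26, from −0.17 for Fkbp5 to 0.66 for Cdkn1a. Histone genes, whose mRNAs are made mostly without a poly(A) tail, had a median of 0.30, with members from −5.09 to 2.27. Complex I genes had a median of 0.13, from −0.17 for Ndufb9 to 0.33 for Ndufb3. Presynaptic genes had 0.14, with Snap25 at 0.22, and clock genes 0.11, from −0.09 for Clock to 0.46 for Per1. Ribosomal protein genes had a median of −0.03, 34 of 79 being higher, and choroid plexus genes −0.32 over 3 members. With the Y-linked list, at −10.33 with the prior count and −3.74 by TPM with a pseudocount of 1, a size set by those constants at 1 to 3 counts in replicate 2, these make 22 of 36 lists outside the central 95% of random lists, 14 above and 8 below. Random lists hold unrelated genes, whereas members of a list can vary together and 1 library stands on each side, so this count has no chance level to be set against. Lists also share members, so the 22 are not separate groups. Sst, Vip, Npy and Cck are in both the neuropeptide and GABAergic lists, and Per1 is in both the clock and glucocorticoid lists. Deposited TPM place the median of all genes at −0.12, and on that scale the excitatory and presynaptic medians were −0.024 and −0.010, which are higher than that median but inside the central 95%. The choroid plexus and ribosomal protein lists were also inside it on that scale. Without their most abundant member, the excitatory and presynaptic lists were inside it too.

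The remaining lists lay inside the central 95%, with medians of −0.03 for deep layer, 0.06 for astrocyte, 0.36 for ependymal, 0.09 for olfactory bulb, −0.07 for thalamus, 0.10 for hypothalamus and 0.03 for immature cell genes. On the TPM scale the astrocyte, olfactory bulb, hypothalamus, immature cell and postsynaptic medians were −0.05, −0.05, −0.02, −0.10 and −0.04, above the −0.12 of all genes, and the neuromodulator receptor median was −0.13, below it. Nr4a2 at 1.03 set the top of the deep layer range and Sulf1 at −0.23 its bottom, and Aqp4 at −0.37 and S100b at 0.23 bounded the astrocyte genes. Glutamate receptor genes had a median of −0.03, from −0.58 for Grin3a to 0.33 for Grin2a, GABA-A receptor genes −0.00, from −0.59 for Gabrg1 to 0.31 for Gabrd, and sodium channel genes −0.01, from −0.19 for Scn2a to 0.96 for Scn4b. Postsynaptic genes had a median of 0.09, with Nlgn1 at −0.12, heat shock genes −0.00, with Hspb1 at 0.50, and neuromodulator receptor genes 0.00, from −1.68 for Htr2c to 1.0997 for Drd2. Mitochondrially encoded genes had −0.01, from −0.69 for mt-Co2 to 0.55 for mt-Cytb, and mt-Co2 and mt-Co3, whose −0.01 is the median, share reads with nuclear copies. On the TPM scale the mitochondrially encoded list lay outside, at percentile 99.8, and among autosomal genes alone, an alternative chosen after seeing the data, the postsynaptic list did, at percentile 97.8. The hippocampus and X inactivation lists had under 3 members at 1 TPM and got no percentile.

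**Figure D2:**
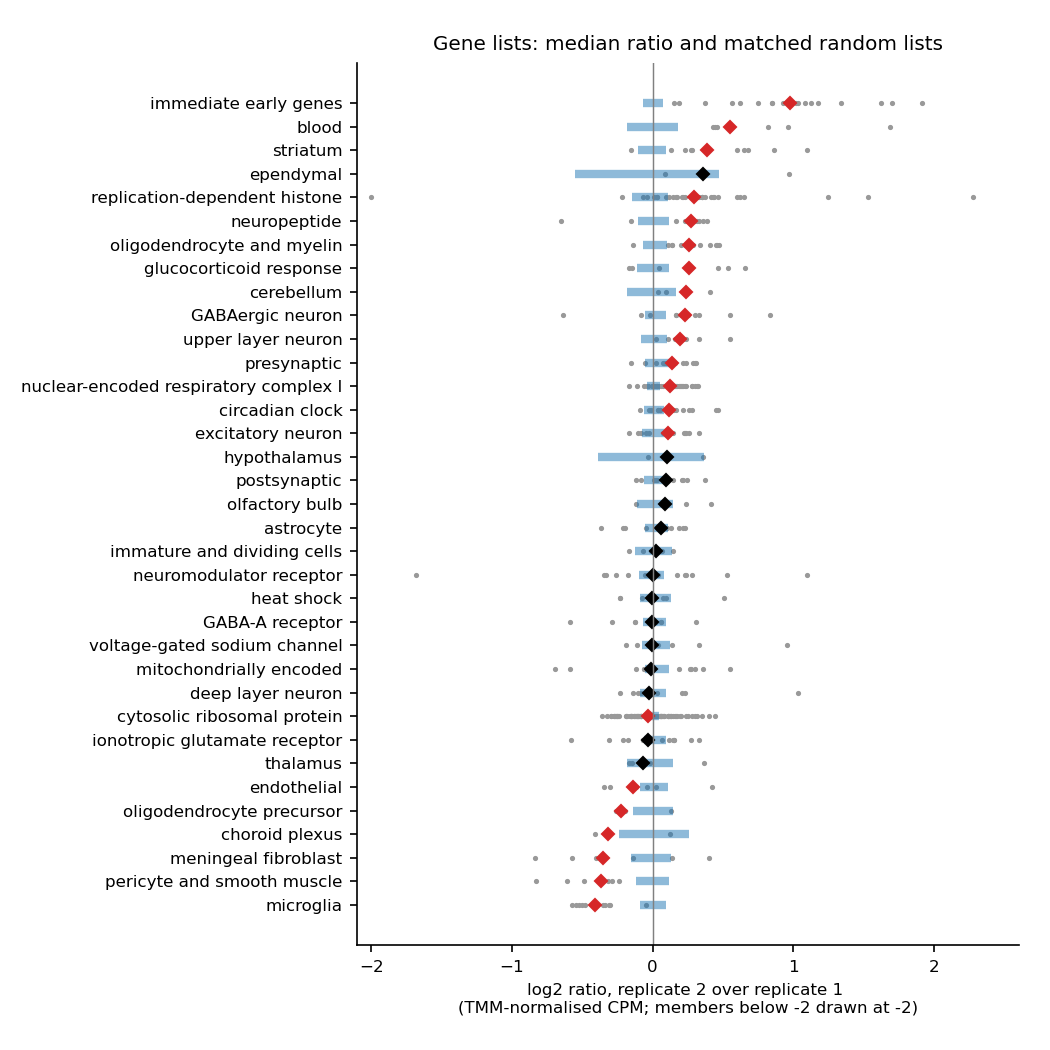
Median log2 ratio of replicate 2 over replicate 1 for each gene list with a percentile except the Y-linked list, as diamonds (red when outside), with members as points and the central 95% of random lists as bars. Immediate early genes lie at 0.98, microglial genes at −0.41 and mural cell genes at −0.37.

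Members of the fixed lists included, the 10 highest ratios among protein-coding genes at 10 TPM or more whose intervals of TPM lay apart were Fos 1.62, Hbb-y 1.58, Prl3b1 1.46, Arc 1.34, Sct 1.26, Tpbpa 1.25, Egr4 1.18, Nr4a1 1.12, Cox6a2 1.11 and Junb 1.08. Hbb-y, an embryonic globin, stood at 9.94 and 27.6 TPM (chromosome 7, 103851749 to 103853216), and the placental hormone gene Prl3b1 at 13.4 and 33.9 TPM (chromosome 13, 27241847 to 27249683). The lowest were Eif2s3y, then Csnk1g3 −1.50, Abi3bp −1.21, Gm11273 −1.08, Rpl10-ps3 −1.08, Ccn3 −1.005, Crym −0.87, Rpl9-ps6 −0.82, Rps12-ps3 −0.77 and C1ql3 −0.73. Abi3bp, of the extracellular matrix, stood at 18.4 and 7.38 TPM (chromosome 16, 56477878 to 56690135), the secreted matrix protein gene Ccn3 at 45.9 and 20.8 TPM and the synaptic secreted protein gene C1ql3 at 32.9 and 18.1 TPM. Csnk1g3, Gm11273 and the 3 Rpl and Rps copies have fractional counts from reads shared with other loci, so their ratios are uncertain.

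Across all genes the replicates were close. Pearson's r of log2(TPM + 1) was 0.984 and Spearman's rho 0.986 over 14919 genes, which are not independent replicates. Of 14599 genes at a mean of 1 TPM or more, 559 (3.83%) lay beyond 1.5-fold, 247 higher and 312 lower in replicate 2, and 211 (1.45%) beyond 2-fold, 102 higher and 109 lower. Among 13247 protein-coding genes, 99 lay beyond 2-fold, 67 higher and 32 lower. The split beyond 1.5-fold depends on the scale, being 157 higher and 295 lower by TPM with a pseudocount of 1, 209 and 520 with 0.1, 214 and 377 by library size and 217 and 356 by the spike-in total. The biological coefficient of variation was 0.113 over 18418 genes, falling from 0.229 at low to 0.0997 at middle and 0.0700 at high counts. Over autosomal genes alone, an alternative chosen after seeing the data, it was 0.107. The coefficient measures the spread between the replicates, which holds technical variation and any effect of the sex-linked split. Intervals of TPM were apart for 4723 of 7929 protein-coding genes at 10 TPM or more, with 1694 higher and 3029 lower in replicate 2 on the TPM scale, where the median of all genes lay at −0.12.

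**Figure D3:**
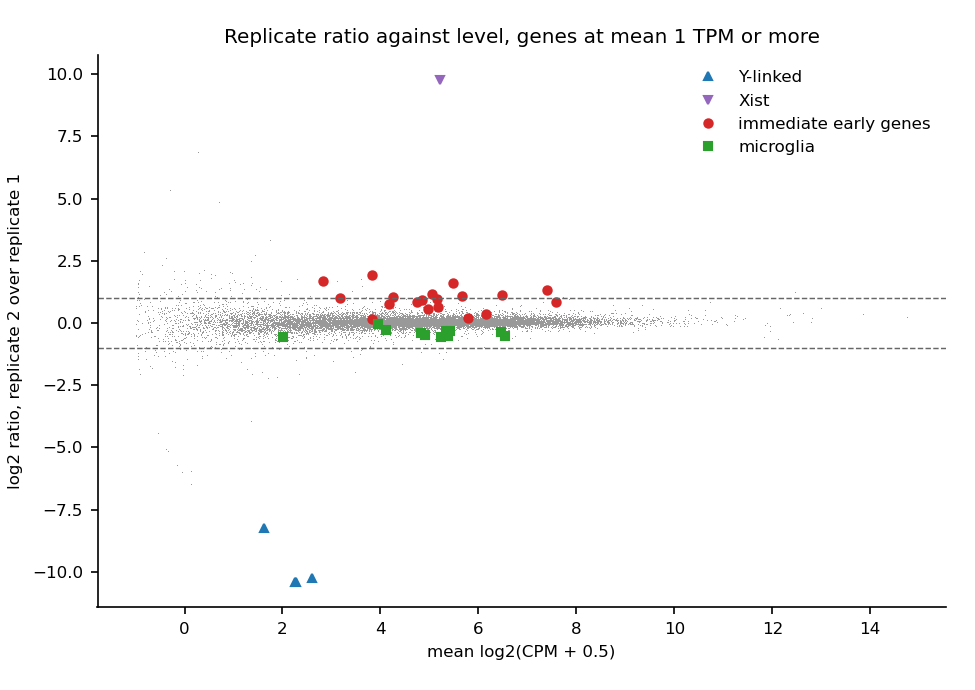
Log2 ratio of replicate 2 over replicate 1 against mean log2 CPM (scaled counts) for genes at a mean of 1 TPM or more, with a prior count of 2 and dashed lines at 2-fold. Xist at 9.76 and the 4 Y-linked genes, from −10.41 to −8.25, lie far from the other genes.

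Leading transcripts of synaptic and other named genes were mostly shared by the replicates. Snap25-201, 1 of the transcripts for the vesicle fusion protein, took 87.5 ± 3.75% of gene TPM and Snap25-202 12.4 ± 3.75%, both with a coding sequence of 618 nt. Camk2a-203 took 97.1 ± 0.0574%, Gnas-208 83.1 ± 0.572%, Pkm-202 80.0 ± 0.592%, Dlg4-201 79.0 ± 1.36% and Mbp-211 74.2 ± 0.644%. Map2-201 took 33.99 ± 5.23%, and App has 1 transcript in the files. Of 27 fixed genes with 2 or more transcripts, 26 had 1 leading transcript in both libraries, the exception being Syn1, whose Syn1-202 took 49.9% and 51.4%. The leading transcript by TPM was not the leading 1 by counts for Gria2, Ank2 and Ank3 in both libraries, for Homer1 in replicate 2 alone and for Syn1 in replicate 1 alone.

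Over 6268 genes at 10 TPM or more with at least 2 transcripts, 5818 (92.8%, Wilson interval 92.2 to 93.4%) had the same leading transcript in both replicates and 450 had different ones. The leading share differed by a median of 2.76 points, and by more than 20 points for 69 genes. Transcript shares are model estimates, and short transcripts gain share by TPM.

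The 56 ERCC spike-ins with 100 or more counts in both libraries had log2 ratios with an SD of 0.14 around their own median, beside 0.23 (0.17 to 0.41) for genes matched on count. Of these spike-ins, 40 lay within 1.1-fold of the median and the largest deviation was 0.45. Their median ratio stood 0.06 above the scaling taken from genes. A chi-square test of counts between the libraries gave 1071329 over 20312 genes (20311 degrees of freedom, 52.7 per degree), and 42.2 per degree for 70 spike-ins. The test treats reads as independent, and the spike-in value shows that technical variation alone exceeds that assumption, so the test does not separate technical from biological differences.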

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

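PhiX, the bacteriophage used as a sequencing control, is outside the measured genes, and its reads lay above the 3 counts that a count of 0 allows. It took 602828 counts in replicate 1, 0.568% of expected counts (Wilson interval 0.567 to 0.570%), and 483074 counts in replicate 2, 0.534% (0.532 to 0.535%). The series has no control samples to set these values against. No explanation for the phiX reads was tested, and no biological explanation was tested.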

How the results depend on the processing

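Alternatives on autosomal genes, short effective lengths, protein-coding genes for detection and the spike-in total for lists were chosen after seeing the data. The count of detected genes stayed within 1.5 times its value under every alternative run, from 14436 to 14693 with 1 library left out. The mitochondrial share was 8.00% by expected counts and 14.3% without genes of effective length under 50 nt, since TPM divides by effective length, and 33.9 to 34.99% with 1 library left out. The other 16 shares of composition also moved by counts. Pearson's r was 0.968 and 0.943 with pseudocounts of 0.1 and 0.01 and 0.995 with no filter, where Spearman's rho was 0.962 against 0.986. The coefficient of variation was 0.130 with no filter and 0.0893 at 10 TPM or more. Genes beyond 2-fold numbered 45 at 10 TPM or more and 2304 with no filter, against 211. The percent of genes with the same leading transcript was 95.3% by counts, 91.9% for genes at 1 TPM or more and 91.5% for transcripts at 5% or more. Where no reason is given, the cause was not tested.

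With deposited TPM, which shift the median of all genes to −0.12, the excitatory and presynaptic medians changed sign to −0.024 and −0.010. Without their most abundant member, the choroid plexus, ependymal and hypothalamus lists had under 3 members at a mean of 1 TPM and got no percentile. The number of lists outside the central 95% was 19 with deposited TPM, 19 of the lists left without the most abundant member and 22 under the other alternatives. Of these, the DESeq2, library size and spike-in scalings shift all genes nearly alike, so they could hardly move a percentile. Among autosomal genes the 22 include the postsynaptic list and no longer the Y-linked list. Among the lists outside the central 95%, no other median changed sign under the alternatives run. Among the lists inside it, medians near 0 did so: the astrocyte, olfactory bulb, hypothalamus, immature cell, mitochondrially encoded, postsynaptic and neuromodulator receptor lists with deposited TPM, and the immature cell, neuromodulator receptor, heat shock, mitochondrially encoded, GABA-A receptor and glutamate receptor lists under at least 1 other alternative. Rescaling TPM to nuclear protein-coding genes multiplies every list level by 1.98 in replicate 1 and 2.08 in replicate 2. Over that alternative and posterior means, list levels moved by more than their SD in 38 comparisons and not in 38. Pair ratios moved in 21 comparisons by posterior means or counts and not in 33, 26 of 27 kept their direction by counts and 27 of 27 had intervals of TPM apart in each single library. Depth limits ratios of genes with few counts.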

Other observations

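The tests of pooled sexes in each library, of prolactin paralogs, of scaling, of striatal tissue and of the sex of the animals for the immediate early genes were chosen only after the result was seen. Noncoding RNAs were among the most abundant transcripts. Gm42418, which overlaps ribosomal RNA sequence, stood at 10925 ± 1039 TPM (SD, n = 2) with a log2 ratio of replicate 2 over replicate 1 of 0.33. The small nuclear RNA gene Rn7sk stood at 5143 ± 793 TPM, with an effective length of 124 nt in replicate 1 and 115 nt in replicate 2. Its expected counts were 46908 and 49194, beside 565144 and 466079 for Meg3. Its rank by TPM therefore rests on that short length. The imprinted noncoding genes Meg3 and Rian reached 1873 ± 93.8 and 1039 ± 116 TPM, with a ratio of 0.00 for Meg3. The nuclear noncoding RNAs Malat1, Miat and Snhg14 reached 944 ± 95.6, 202 ± 59.8 and 182 ± 11.8 TPM, with ratios of 0.29 for Malat1 and −0.27 for Miat. Gas5, the host of small nucleolar RNAs, stood at 389 ± 45.0 TPM.

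Mitochondrial transcripts shared reads with nuclear copies on chromosome 1 between 24612407 and 24616197. The pair mt-Co2 and mt-Atp6 together had a log2 ratio of −0.64 and the nuclear copies Gm10925 and Gm28661 together 0.92, whereas all 4 together had 0.23. The separate values of mt-Co2 and mt-Atp6 are therefore uncertain. The same holds for mt-Co3 and its nuclear copy Gm28437, whose counts have a posterior SD of 129574 in replicate 1 and 91790 in replicate 2, beside 734445 and 598715 counts for mt-Co3.

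Xist and the 4 Y-linked genes split the replicates, against labels that describe males and females pooled. If each library held both sexes, Xist in replicate 1 and at least 1 Y-linked gene in replicate 2 would reach 5% or more of the other library, and the highest of the 5 was 0.205%, for Uty. If each library held 1 sex, X-linked genes that escape inactivation would be higher in replicate 2, and Kdm5c at 0.41, 5530601H04Rik at 0.39, Ddx3x at 0.26 and Kdm6a at 0.15 had a median log2 ratio of 0.32, at percentile 99.96 of random lists, where 503 X-linked genes had a median of −0.05. The values argue against pooling within each library at shares of 5% or more and are consistent with male tissue in replicate 1 and female tissue in replicate 2, so the label may describe the pair of libraries. Whether another label is wrong stays open, and a difference in biology between the sexes was not tested.

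Placental and fetal genes were present at low levels in both libraries and higher in replicate 2, beginning with Prl3b1, Tpbpa and Hbb-y. Of 35 placental genes, 5 reached 1 TPM in both libraries, 30 of 30 with 10 or more counts were higher in replicate 2 with a median log2 ratio of 1.53, and Tpbpb, the most abundant, stood at 2.51 and 6.94 TPM. Some of these 30 had counting intervals that span no change. Among them was Psg16 at 0.09 (−0.15 to 0.34), which by TPM stood at 1.64 in replicate 1 and 1.44 in replicate 2. The 18 members outside the prolactin family had a median of 1.48 ± 0.893 (SD across genes), which argues against reads shared between prolactin paralogs as the whole cause. If RNA or reads of a placental or fetal sample were in both libraries, a second placental list would lie between 0.8 and 1.8, and its 15 genes with 10 or more counts, of 25 listed, 3 of which reached 1 TPM in both, had a median of 1.72 ± 0.681 (SD across genes), led by Prl2c3 at 4.64 and 14.2 TPM, with 15 of 15 higher. That median lay in the band, but the band was set after higher placental ratios had been seen. Many genes of the second list are also of the Prl and Psg families of the first. Single ratios differed beyond their counting intervals, with Psg16 at 0.09 and Ctsr at 3.45 (2.70 to 5.17). The values therefore cannot decide whether there was such a source. It may be other tissue, RNA or reads from other libraries, and the values do not tell these apart.

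The same comparison was made for other tissues. All 3 fetal erythroid and fetal liver genes were higher, with a median of 1.63 and Hba-x at 2.74 and 7.23 TPM, and 3 reached 1 TPM in both libraries. Liver genes with 10 or more counts were higher for 7 of 7 with a median of 2.10, 2 reached 1 TPM in both and Apoa2 led at 2.04 and 2.58 TPM. Skeletal muscle genes were higher for 6 of 6 with a median of 1.03, and Acta1, the only 1 at 1 TPM in both, stood at 10.5 and 12.2 TPM. Among the other lists, Ighm of B cells stood at 24.0 and 23.8 TPM, Lgals4 of intestine at 6.92 and 5.27 TPM, Krt10 of skin at 3.22 and 2.71 TPM, Cidea of fat at 2.16 and 1.90 TPM and Lck of T cells at 2.01 and 1.70 TPM. At 1 TPM or more in both libraries were 3 heart, 2 skin and 1 each of the intestine, T cell, B cell and fat genes, and none of the rest. Adrenal genes gave 2 of 2 and 1.55, spleen and B cell genes 4 of 4 and 0.45, intestine genes 2 of 4 and 0.68, pancreas genes 1 of 2 and 0.66, stomach genes 1 of 1 and 0.27, and fat genes 2 of 4 and 0.16. Skin genes gave 1 of 2 and 0.00, thymus and T cell genes 2 of 5 and −0.01, heart genes 2 of 4 and −0.05, with Nppa at 7.17 TPM in both, bladder genes 1 of 3 and −0.21, kidney genes 1 of 4 and −0.56, and lung genes 0 of 1 and −0.86. No testis or mammary gland gene had 10 counts.

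Immediate early genes were higher in replicate 2 for 19 of 19, with a median log2 ratio of 0.98. A scaling shifts every gene alike, so as the cause it needs a list median near that of all genes, and the list lay above all genes by 0.98, more than the SD of its members, 0.475. More striatal tissue as the cause was taken to need a striatal median at or above that of the immediate early genes. That holds only if striatal list members are more specific to striatum than immediate early genes, which was not tested. The striatal median lay below by 0.59, more than the SD of its members, 0.34, and members ranged from −0.15 to 1.0997. The comparison therefore cannot decide on striatal tissue. Both comparisons restate list medians that had already been seen, so they are not independent tests. The sex of the animals cannot be told apart from the replicate, since 1 library had the Y-linked transcripts and the other had Xist. Handling and time to dissection are not given and were not tested, so the difference between the replicates may be biological or of handling.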
